A study of Mus musculus with 6 samples.

How the data were processed

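Total RNA from mouse wounds was labelled with biotin and hybridised to Illumina bead arrays, per the labels. The 6 arrays fall into 4 groups by their titles: stabilised (1), GFP control (1), tamoxifen knockdown (2) and tamoxifen control (2). The labels call the samples biological replicates, of a C57/BL6 background.

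The deposited non-normalized table gives, per the file headers, an average signal intensity and a detection p-value for each of 45281 probes and each array. The lowest intensity was 84.7 and array medians ran from 136 to 152, so the deposited intensities were neither background-subtracted nor scaled between arrays. The deposited detection p-values come in steps of 1 in 936. A second deposited table holds log2 values with equal quantiles on every array, and these lie within 0.0874 of the output of limma's neqc on the intensities, with array medians of 5.12 log2. R 2.14 is the only tool in the submitters' processing notes, and the scanner software, background setting and normalization are not given in the sources used here. Stray text made up 2 lines of the non-normalized table (0.00442%), which were dropped.

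Probe names came from the platform annotation: 34885 probes had 1 gene symbol, 18 had several and 10378 had none. Symbols were looked up by gene identifier in a RefSeq gene table of assembly GRCm38.p6, which changed 0 of them. No coordinates are printed, and no gene is named from a probe with several symbols. Of the 610 symbols of the gene lists, 2 matched no gene.

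Intensities were background-corrected, quantile-normalized and put on the log2 scale with neqc (limma 3.58.1, R 4.3.3, offset 16) over all 6 arrays. For knockdown against tamoxifen control, probes with a detection p under 0.01 on at least 2 of the 4 tamoxifen arrays were kept, and the probe with the highest mean over the 6 arrays stood for its gene, which left 9855 genes. They were tested with limma (lmFit with 1 mean per group, default eBayes, two-sided, Benjamini-Hochberg, adjusted p under 0.05), with 2 residual degrees of freedom. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists with at least 3 measured genes, and counts of members past the threshold were taken over all genes and adjusted over the list alone. For stabilised against GFP control, genes with a detection p under 0.01 on at least 1 of the 2 arrays were compared by the log2 difference, counted from 2-fold. List medians were set against 10000 random lists matched on mean level in 20 bins.

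The 29 lists cover Wnt targets, Wnt pathway, collagen and matrix, contractile, fibroblast, TGF-beta, cell cycle, macrophage, neutrophil, inflammation, protease, endothelial, basal and differentiated keratinocyte, hair follicle, skeletal muscle, muscle regeneration, adipocyte, sebaceous, interferon, lymphocyte, erythroid, mast cell, nerve, melanocyte, cartilage and bone, hypoxia, immediate early and sex-linked genes. These lists, the tests, the thresholds, the alternatives and the rule for named genes were set before the data were examined, apart from the tests and alternatives that the text names as chosen later.

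A gene whose probes all had a detection p of 0.01 or more on every array of a group was called below detection there. Its fold is given as at least N-fold, the bright group's mean minus the dim group's mean of, per array, the higher of the lowest normalized signal among detected probes (5.92 to 6.27 log2) and the probe's own value. For Fgfr1op2 and Pmel, where the brightest probe alone was below detection in 1 group, the bound is that probe's. Named genes are Ctnnb1 and sex-linked genes. For knockdown they are the 10 largest differences each way among genes past the threshold with groups that do not overlap, filled by size from genes with an unadjusted p under 0.05 and groups that do not overlap. For the adenovirus pair they are the 10 largest each way among genes detected on both arrays, and 5 each way detected on 1 array, by bound. Between comparisons they are 5 genes in each sign class by the smaller of the 2 sizes, and in each list up to 4 members by unadjusted p or by size. A few other genes are named after their values were seen, as the text says or because a count of 5 or fewer called for it.

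The limma step was tested on simulated data with the levels of the 9855 genes of the knockdown comparison, 200 of them changed. Spreads were drawn from limma's fitted prior (SD 0.19 log2), with noise independent between genes and no axis of age or tissue. The limma step recovered 2% of 2-fold, 82% of 4-fold, 84% of 8-fold and 96% of 16-fold changes at an adjusted p under 0.05, with 4 false calls. Given that noise, these shares can overstate the recovery on the real arrays. Any pair of arrays shared at most 2 identical raw signals over the 45281 probes, so none was a duplicate. The alternatives covered background correction, scaling, the deposited log2 values, the detection filter, the choice of probe, the variance model, thresholds, set tests, a replicate block and leaving out each tamoxifen array.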

Results

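Gene expression was measured in full-thickness wounds of mouse dorsal skin, 8 days after injury, on 6 Illumina bead arrays. Beta-catenin, encoded by Ctnnb1, carries the canonical Wnt signal into the nucleus, and its level was changed before wounding in either direction. In 1 experiment, mice with a floxed exon 3 of Ctnnb1 were given an adenovirus with Cre recombinase or, as the control, with GFP, 1 array each. Loss of exon 3 gives a protein that escapes degradation, and that array is called stabilised here. In the other experiment, mice with floxed exons 2 to 6 were all given tamoxifen, and those of the 2 knockdown arrays also carried a Cre-Esr1 gene that those of the 2 tamoxifen control arrays lacked. Replicate 1 of each tamoxifen group came from a mouse aged 5 months, and the 4 other mice were aged 2 months. Between 15217 and 16656 of the 45281 probes had a detection p under 0.01 on an array, and the number of arrays limits the precision of every value below.

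Ctnnb1 itself was read by 4 probes. On the brightest, the normalized log2 intensity was 11.86 ± 0.05 (SD, n = 2) in knockdown and 11.73 ± 0.40 (SD, n = 2) in control wounds, a log2 fold change of 0.13 (adjusted p = 0.983 in limma). The difference was -0.15 without control replicate 2. The 3 other probes gave log2 differences of 0.14, 0.20 and -0.30. The stabilised array read 11.37 and the GFP control array 11.46. Whether any probe lies in the floxed exons is not given in the sources used here, so these values do not check the labels. Xist, the RNA of the inactive X chromosome, was detected on both adenovirus arrays (log2 10.41 for GFP and 10.11 for stabilised) and read 4.59 to 4.66 on the 4 tamoxifen arrays. The Y-linked gene Eif2s3y read 8.79 to 9.07 on the tamoxifen arrays and 4.59 to 4.60 on the adenovirus arrays. The sexes therefore differed between the 2 experiments and not within either comparison.

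The first comparison asked what loss of beta-catenin does to the wound. No single gene passed the threshold, while groups of skin and muscle genes were lower in knockdown wounds by camera with its preset correlation. No group passed with an estimated correlation, the smallest adjusted p being 0.606, but with 2 residual degrees of freedom that test could hardly pass. The estimated correlation was far above the preset for many lists, 0.934 for skeletal muscle genes, so the preset test can overstate their calls. Basal keratinocyte markers had a median log2 fold change of -0.99, skeletal muscle genes of -1.80 and genes known to be induced by Wnt signalling of -0.35. The muscle difference lay almost wholly between the arrays of replicate 1, as given below. Matrix proteases had a median of 0.26, or 0.03 without knockdown replicate 1, and neutrophil markers of 0.81, or -0.22 without knockdown replicate 2. Of the 9855 genes tested with limma, 0 had an adjusted p under 0.05, 433 had an unadjusted p under 0.05 where chance alone gives 493, and the smallest adjusted p was 0.254. Treat with a minimum of 1.2-fold and a trended, robust variance also called 0 genes, with 186 and 404 at an unadjusted p under 0.05. These p-values measure the spread between arrays that the labels call biological replicates. In both tamoxifen groups the 2 replicates also differ in age, so the spread holds any effect of age. With a block for replicate number, which matches age, more genes than chance gives had an unadjusted p under 0.05, as given below. The 2 groups did not overlap for 3265 genes, or 33.1%, where chance gives 33.3%. Without knockdown replicate 1, 7 genes passed, each with an adjusted p of 0.0437: Osm, Tnf, Ccl3, Ccl4, Il1b, Slc2a3 and Cxcl1. That fit takes its spread from the control group and assumes that the lone knockdown array varies like it, and Tnf, for example, read 10.45 on knockdown replicate 2 and 6.18 on replicate 1.

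The genes named next have the largest differences among those with an unadjusted p under 0.05 and groups that do not overlap, and none passed the threshold. Among the differences larger than most of theirs, but outside that limit, were those of Cxcl2 (4.64), Il1b (3.17), Ccl4 (2.87) and Cxcl1 (2.83). Retnlg, a neutrophil product, was at 9.48 ± 0.73 (SD, n = 2) in knockdown and 6.18 ± 0.69 (SD, n = 2) in control wounds, 9.88-fold higher with an adjusted p of 0.889. Saa3, an acute-phase protein, read 11.31 ± 1.01 against 8.60 ± 0.07 (SD, n = 2 each). The collagenase Mmp13 was close between replicates, at 12.65 ± 0.01 against 11.41 ± 0.10 (SD, n = 2 each), although its 3 probes gave log2 differences from 0.19 to 1.24. The stromelysin Mmp3 had a log2 difference of 1.44, and its 3 probes gave 1.35 to 1.51. Atf3, Fosb and Fos, transcription factors of the immediate early response, differed by 1.57, 1.33 and 1.21. Their knockdown SDs were 0.73, 0.78 and 0.81 (n = 2), with knockdown replicate 2 the higher array for each. Lyzl4, Bglap2 and the coagulation factor gene F10 differed by 1.25, 1.17 and 1.17.

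Among the lowest genes, Krt2, a keratin of the upper epidermis, read 7.09 ± 1.73 in knockdown and 11.56 ± 0.65 in control wounds (SD, n = 2 each), a log2 fold change of -4.47 with an adjusted p of 0.976. The muscle genes Mylk2, Sln, Mybpc2 and Myh4 had log2 fold changes of -2.88, -2.65, -2.55 and -2.50. Mylk2 and Myh4 were below detection on both knockdown arrays, which makes them at least 4.71-fold and 3.28-fold lower. The kallikrein genes Klk1b26, Klk1b1 and Klk1 had log2 fold changes of -2.51, -2.48 and -2.40, with Klk1b1 at least 2.86-fold lower, and probes of such near-identical family members can read each other. Serpina3b and Wfdc3 followed at -2.81 and -2.54. The 2 knockdown arrays differed for Serpina3b, at 6.57 on replicate 1 and 9.60 on replicate 2, against a control mean of 10.89.

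The 29 gene lists fixed before the data were examined gave 25 with at least 3 measured genes, and 14 of these passed camera's test at an adjusted p under 0.05 with its preset correlation. With an estimated correlation 0 passed, the smallest adjusted p being 0.606, and fry called 0. Both of these tests rest on the 2 residual degrees of freedom, so they could hardly pass and decide little about the 14 calls. Interferon genes, with an estimated correlation of 0.0013 against the preset 0.01, had the smallest unadjusted p in that camera test, 0.0944. The other called lists had estimated correlations above the preset, from 0.068 for Wnt targets to 0.962 for regenerating muscle, with 0.934 for skeletal muscle. If these estimates hold, the preset understates the spread of such lists, and its small adjusted p can overstate the calls. No member of any list passed over all genes tested. Only 3 of the 14 calls, skeletal muscle, basal keratinocyte and protease, held without each tamoxifen array in turn.

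Skeletal muscle genes were lower in all 26 measured members (camera adjusted p = 1.35e-13, and 0.606 with an estimated correlation). Of these, 0 passed when adjusted over the list alone. Atp2a1, the calcium pump of fast fibres, had a log2 fold change of -2.21 and Actn3 of -1.85. The list's median difference between the 2 knockdown arrays, -2.08, was as large as that between the groups, and the group difference was -0.70 without knockdown replicate 1 and -2.86 without knockdown replicate 2. All 9 genes of developing and regenerating muscle were lower too, with a median of -1.29 (adjusted p = 9.00e-05, and 0.606 with an estimated correlation), among them Myf6 at -1.75 and Des at -1.33. They averaged -0.75 on knockdown and 1.87 on control replicate 1, but 1.04 and 0.93 on replicate 2. This second muscle list had a median of -0.35 and an adjusted p of 0.145 without knockdown replicate 1, and a median of -2.15 without knockdown replicate 2.

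Basal and wound-edge keratinocyte markers were lower in all 16 measured members (adjusted p = 5.13e-12, and 0.606 with an estimated correlation), and 4 passed when adjusted over the list alone. Krt17, a keratin of the wound edge, read 13.15 ± 0.68 in knockdown and 14.77 ± 0.30 in control wounds (SD, n = 2 each). Krt15 had a log2 fold change of -1.55, the laminin chain gene Lamb3 of -1.02 and the integrin gene Itgb4 of -0.96. The median stayed between -0.64 and -1.24 without each array in turn. Suprabasal and cornified epidermis genes had a median of -0.10 over 30 genes, 13 of them higher and Krt2 the lowest at -4.47, and camera made no call.

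Wnt target genes were lower in 11 of 14 measured members (adjusted p = 0.00168, and 0.606 with an estimated correlation), with 0 adjusted over the list alone. Axin2, a feedback inhibitor that Wnt signalling induces, read 8.30 ± 0.31 in knockdown and 9.11 ± 0.19 in control wounds (SD, n = 2 each), a log2 fold change of -0.81. Bmp4 and Sox9 had log2 fold changes of -0.60 and -0.59, and Wif1, below detection on both knockdown arrays, was at least 1.31-fold lower. With the 2 members that were below detection in 1 group set at their bounds, the list's median was -0.27. The call ended without knockdown replicate 2, at an adjusted p of 0.0842, and the median ran from -0.27 to -0.64 as single arrays were left out. The Wnt ligands, receptors and inhibitors as a list had a median of -0.07 and an adjusted p of 0.504, with Sfrp2, a secreted Wnt antagonist, at 1.15 and 1 gene past the threshold adjusted over the list alone.

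Matrix proteases and their inhibitors were higher in 16 of 19 members (adjusted p = 0.0012, and 0.606 with an estimated correlation), and 2 passed when adjusted over the list alone. Besides Mmp13 and Mmp3, the cathepsin gene Ctsl differed by 0.93 and Mmp10 by 0.67. The median ran from 0.03 without knockdown replicate 1 to 0.44 without control replicate 1. Macrophage markers were higher in 17 of 21 members with a median of 0.13 (adjusted p = 0.00675, and 0.634 with an estimated correlation), with Clec7a, the first member by unadjusted p, at 0.97. That call ended without knockdown replicate 1 (adjusted p = 0.197) or control replicate 2 (0.283), and the median ran from 0.02 to 0.30 as single arrays were left out. Cell cycle genes were higher in all 25 members by a median of 0.21 (adjusted p = 0.00675, and 0.699 with an estimated correlation), a difference of -0.02 without control replicate 2, 0.49 without control replicate 1, and 0.16 with an adjusted p of 0.111 without knockdown replicate 2.

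Inflammatory and immediate early genes were high on 1 knockdown array. Neutrophil markers had a median of 0.81 (adjusted p = 0.00675, and 0.606 with an estimated correlation) and of -0.22 without knockdown replicate 2, and the adjusted p was 0.147 without control replicate 1. Inflammatory cytokines and chemokines had a median of 0.49 (adjusted p = 0.0086, and 0.606 with an estimated correlation), or 0.17 with an adjusted p of 0.218 without knockdown replicate 2. Immediate early genes had a median of 0.63 (adjusted p = 0.00675, and 0.685 with an estimated correlation), or -0.01 without knockdown replicate 2, and an adjusted p of 0.147 without control replicate 1. Without knockdown replicate 1 these 3 medians were 1.78, 0.85 and 1.30. The chemokine gene Cxcl2 read 14.12 on knockdown replicate 2, 6.95 on knockdown replicate 1, and 6.55 and 5.25 on the controls. Hba-a1, a haemoglobin gene, read 14.65 on knockdown replicate 2 and 11.57 to 12.54 on the 3 other tamoxifen arrays.

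The remaining calls were smaller lists or shifts, and each ended when some array was left out. Interferon-stimulated genes had a median of -0.28 over 19 genes (adjusted p = 0.0103, and 0.606 with an estimated correlation). Adipocyte markers had a median of -0.24 over 10 genes (0.0235, and 0.606 with an estimated correlation), with Scd1 at -1.17, and sebaceous gland markers of -0.78 over 7 genes (0.0263, and 0.606 with an estimated correlation), with Fa2h at -1.84. Hair follicle genes had a median of -0.74 over 3 genes (0.00675, and 0.606 with an estimated correlation), or -0.64 with Krt84, at least 1.55-fold lower, at its bound, and 1 gene passed when adjusted over the list alone. Without knockdown replicate 1 the adjusted p was 0.369 for interferon, 0.0873 for adipocyte, 0.401 for sebaceous (median -0.04) and 0.123 for follicle genes. The lists for interferon, sebaceous and follicle genes each had an adjusted p of 0.142 without control replicate 2, where the follicle median was -0.21. The adipocyte list had an adjusted p of 0.627 and a median of -0.09 without control replicate 1. As single arrays were left out, the medians reached -0.86 for adipocyte, -1.57 for sebaceous and -1.18 for follicle genes, and -0.16 at the smallest for interferon genes.

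No call was made for fibrillar collagens and other matrix proteins (median 0.01), contractile proteins (0.16), fibroblast markers (0.04), TGF-beta pathway genes (0.02), endothelial (0.03), mast cell (-0.31), lymphocyte (-0.08), nerve (-0.05) or hypoxia genes (0.13), with adjusted p of 0.0720 or more. The TGF-beta list had a mean of -0.02 and the endothelial list of -0.01, opposite in sign to their medians, and camera ranked the endothelial list down. Elastin, encoded by Eln, had a log2 fold change of -1.02 among the matrix genes, and the smooth muscle genes Actg2, Tagln and Myl9 differed by 0.68, 0.55 and 0.46. Erythroid, melanocyte, cartilage and bone, and sex-linked lists had fewer than 3 measured genes, as the last 2 had on the adenovirus arrays. Of the melanocyte genes, Dct had a log2 fold change of -2.10, and the brightest probe of Pmel, below detection on both knockdown arrays, was at least 2.09-fold lower.

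**Figure D1:**
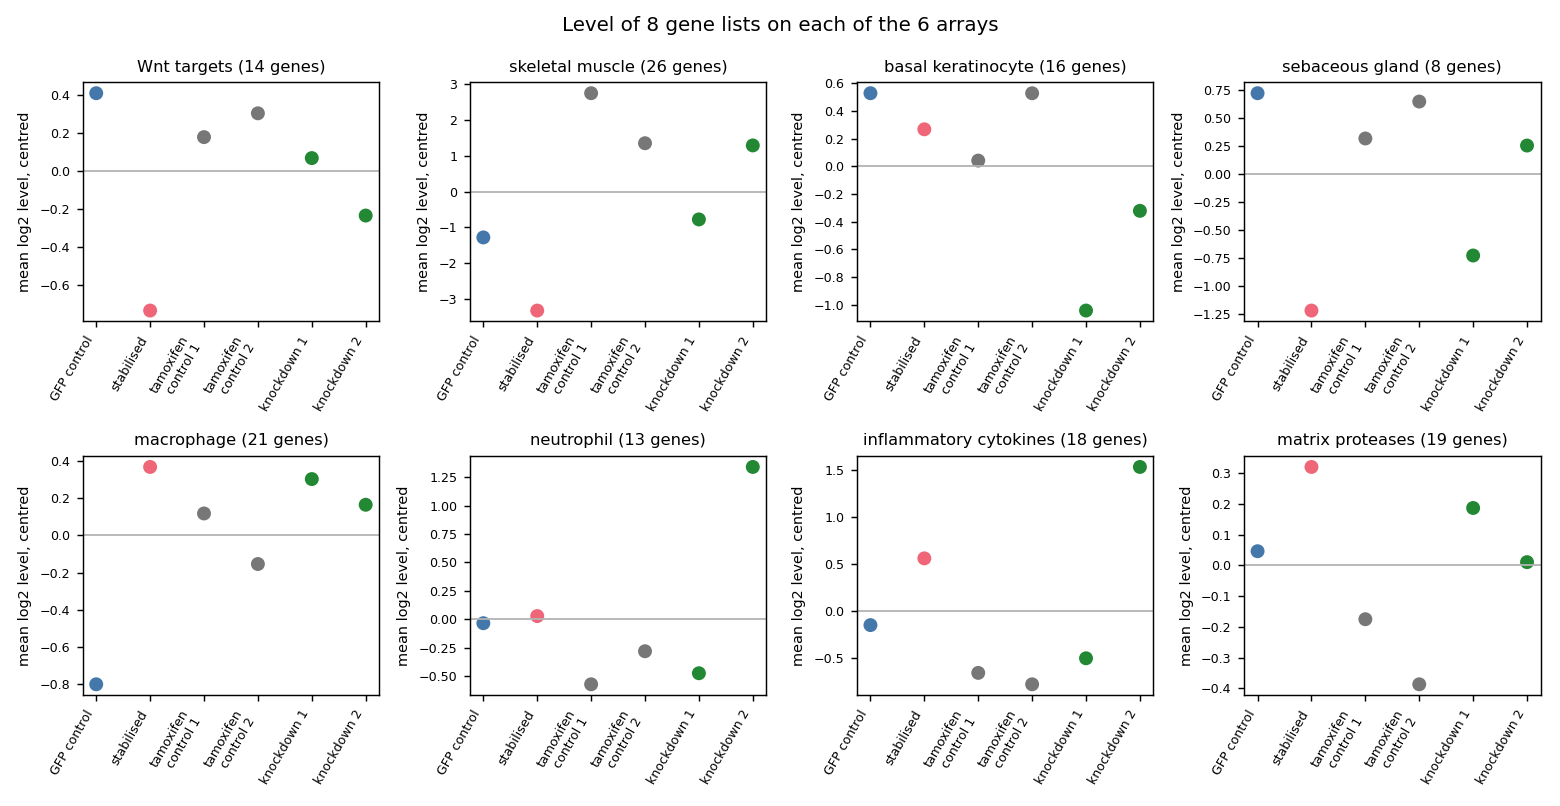
Each panel shows the mean log2 level of a gene list on each of the 6 arrays, after subtracting each gene's mean over the arrays; a point is 1 array, and blue, red, grey and green mark GFP control, stabilised, tamoxifen control and knockdown. Vertical scales differ between panels. Wnt targets sit at 0.41 on the GFP control and -0.73 on the stabilised array, and inflammatory genes reach 1.54 on knockdown replicate 2 alone.

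The second comparison asked what stabilised beta-catenin does to the wound, and rests on 1 array per group, so its differences have no replicate check and no p-value of their own. The stabilised array was lower in genes of skin appendages, muscle and the upper epidermis, and higher in macrophage, haemoglobin and some chemokine genes. Centred on each gene's mean over the arrays, macrophage genes averaged -0.80 on the GFP control and 0.37 on the stabilised array. On the tamoxifen arrays they averaged -0.15 to 0.30, so the GFP control array was the lowest. Part of that gap is the 1 probe of Fcer1g, a member of the list, which read 4.71 on the GFP control array and 12.89 to 14.00 on the others. The follicle keratin genes Krt27 and Krt71 read 9.16 and 9.03 on the GFP control array and 4.53 to 5.94 on every other array. Skeletal muscle genes were lower by a median of -2.47 on the log2 scale and sebaceous gland genes of -1.34, or -1.60 and -0.53 with the 10 of 17 and 4 of 8 members below detection on 1 array at their bounds. Macrophage markers were higher by 0.78. Wnt target genes were lower, not higher, on the array labelled stabilised, with a median of -1.10, or -0.58 at bounds. Of 10002 genes, 280 were at least 2-fold higher and 488 at least 2-fold lower. For scale, 280 of the same genes differed at least 2-fold between the 2 tamoxifen control arrays and 463 between the 2 knockdown arrays. The mice of each of these pairs differed in age, and those of the adenovirus pair did not. Of the 10002 genes, 9095 were detected on both adenovirus arrays, and the rest entered through 1 of them. That filter favours differences in the adenovirus pair over the tamoxifen pairs. The count among genes detected on both, given below, is lower. Scaling by the median in place of quantiles, which moved the median of all genes from 0.05 to -0.13, gave 555 lower and made 19.7% of the differing genes higher, against 36.5%.

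Among genes detected on both arrays, Retnla, a product of alternatively activated macrophages, was 15.0-fold higher on the stabilised array. The haemoglobin genes Hba-a1, Hbb-bt and Hbb-bs were 6.96-fold, 6.92-fold and 6.48-fold higher, the Hbb genes being near-identical copies that probes can fail to separate. The chemokine genes Ccl3 and Ccl4 were 4.92-fold and 4.76-fold higher, and the coagulation factor genes F10 and F7 were 6.06-fold and 4.96-fold higher. Inmt and Adamts19 were 6.24-fold and 5.32-fold higher. The lowest were Sprr4, a cornified envelope gene, at -5.98 on the log2 scale, and the keratin genes Krt79 and Krt15 at -4.91 and -3.91. The lipid enzyme genes Alox12e and Elovl6 were at -4.74 and -4.51, and the skin chemokine gene Ccl27a at -4.32. Mylpf, Cidea and Lce1m were at -3.96, -3.54 and -3.46. The brightest probe of Fgfr1op2 was below detection on the stabilised array and at least 8.84-fold lower, although a second probe was at -0.53.

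Some genes were detected on only 1 of the adenovirus arrays, and their folds are lower bounds. H2-Ea, an MHC class II chain, was at least 173-fold higher on the stabilised array (log2 13.42 against 4.70) and below detection on the 4 tamoxifen arrays as well. Fcer1g, the shared gamma chain of Fc receptors, was at least 120-fold higher, since the GFP control array read 4.71 where the other 5 arrays read 12.89 to 14.00. Ifi205, Hoxc10 and Alas2, the last an enzyme of haem synthesis in red cells, were at least 10.9-fold, 6.53-fold and 5.92-fold higher. In the other direction, the defensin gene Defb6 was at least 96.7-fold lower, and Myl1, Mup2, Fa2h and Cyp2g1 were at least 58.1-fold, 43.2-fold, 36.5-fold and 34.5-fold lower. Over their 3 detected probes each, Myl1 and Mup2 gave log2 differences from -5.98 to -1.75 and from -6.22 to -1.70. H2-Ea, Fcer1g, Alas2, Defb6 and Fa2h each rest on a single detected probe.

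**Figure D2:**
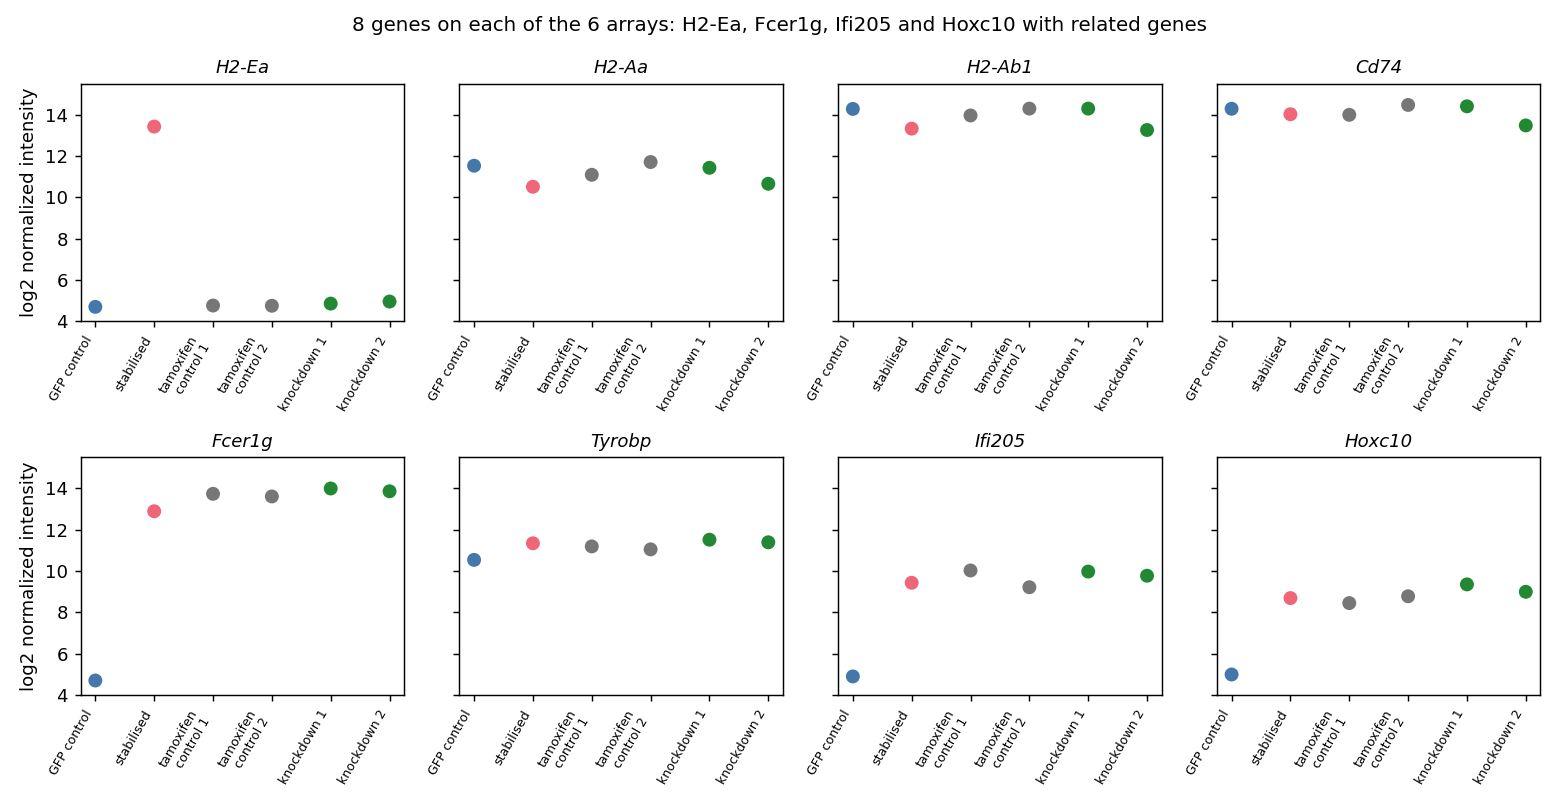
Normalized log2 intensity of 8 genes on each of the 6 arrays (1 point per array, coloured by group as in the panels of gene lists). H2-Ea stands at 13.42 on the stabilised array and under 5 on every other, and Fcer1g at 4.71 on the GFP control array alone, while the related genes H2-Aa, H2-Ab1, Cd74 and Tyrobp are detected on all 6.

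Of the 27 lists with at least 3 measured genes, 15 had a median outside the central 95% of 10000 random lists of the same size and level, 11 of them lower on the stabilised array. Random lists draw their genes singly, while the members of a list can vary together between any 2 wounds. The range is then too narrow, and a median outside it does not tell an effect from such variation. All 17 measured skeletal muscle genes were lower, 15 of them at least 2-fold with bounds for members below detection, with Atp2a1 at -2.69 and Tnni2 at -1.97. All 6 genes of regenerating muscle were lower, with a median of -1.88. Hair follicle genes had a median of -1.62, with Krt73 at -2.42, sebaceous genes of -1.34, and adipocyte genes of -1.09, with Scd1 at -3.17. The suprabasal epidermis list had a median of -0.57, with Flg2 at -2.27, while the basal keratinocyte list was at -0.01. Melanocyte (-1.20, 3 genes), contractile (-0.38), lymphocyte (-0.36) and Wnt pathway genes (-0.14) were also below the random range, and the Wnt pathway median was above 0 under other detection filters. Where members lay below detection on 1 array, setting them at their bounds gave medians of -1.60 for muscle, -0.52 for regenerating muscle, -0.82 for follicle, -0.53 for sebaceous, -0.10 for adipocyte and -0.38 for melanocyte genes. At their bounds, the regenerating muscle, adipocyte and melanocyte medians lie inside the random ranges (-0.74 to 0.47, -0.39 to 0.30 and -1.09 to 0.69), so these 3 calls rest on values below detection.

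Wnt target genes were lower on the array labelled stabilised in 13 of 14 members, 5 of them at least 2-fold with bounds for members below detection, the exception being Cd44. Nkd2, Apcdd1, Sox9 and Bmp4 were at -1.86, -1.72, -1.34 and -1.26, and Axin2 was at -0.65. With 4 members at their bounds the median was -0.58. Macrophage markers were higher in 18 of 21 members, with Cd163 at 2.01, Mrc1 at 1.38 and Ctss at 0.98. Inflammatory genes were higher in 15 of 18 (median 0.38), with Ccl6 at 2.19 and Cxcl2 at 2.15, and endothelial markers in 17 of 18 (median 0.41), with Cd34 at 1.31 and Tie1 at 1.07. The erythroid list of 3 genes had a median of 3.01, or 2.56 with bounds. Within the random range lay collagen and matrix (-0.10), fibroblast (0.10), TGF-beta (0.13), cell cycle (0.08), interferon (0.10), neutrophil (0.27), protease (0.19), immediate early (-0.10), hypoxia (-0.01), nerve (0.02) and mast cell genes (0.02). The hypoxia and nerve lists had means of 0.07 and -0.29, opposite in sign to their medians.

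Set side by side, genes that differed at least 2-fold in both comparisons mostly went the same way, and over all genes the differences shared a sign for 58.2%. Over the 9568 genes in both, and with no array shared, the log2 differences had a Pearson r of 0.425 and a Spearman rho of 0.266 across genes, which are not independent replicates. Of 126 genes at least 2-fold different in both, 102 were lower in both, 18 higher in both and 6 opposite. Lower in both were Serpina3b (-2.81 in knockdown), Wfdc3 (-2.54), the sarcomere gene Tcap (-2.29), Ces1d (-2.28) and the keratin gene Krt24 (at least 1.99-fold). All 5 were below detection on the stabilised array, at least 7.47-fold, 12.1-fold, 2.11-fold, 17.3-fold and 3.28-fold lower in that order. Higher in both were Cxcl2 (4.64, 2.15), Ccl4 (2.87, 2.25), Saa3 (2.71, 2.00), Ccl3 (2.60, 2.30) and Osm (2.52, 1.53). Apart from Saa3, their knockdown values come from knockdown replicate 2 alone, where Ccl3, for example, read 13.43 against 8.98 on replicate 1. Without knockdown replicate 1 the r was 0.236, and without control replicate 2 it was 0.278.

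Of the 9568 genes, 4002 differed in opposite ways, but of the 126 at least 2-fold different in both comparisons only 6 did. The genes named next lead by the smaller of their 2 sizes, and some are under 2-fold. Fetub, Wfdc12, Krt84 and Adh1 were higher on the stabilised array by 1.25, 1.05, 0.90 and 0.89 and Aldh1a1 at least 2.21-fold. In knockdown wounds Fetub, Wfdc12 and Adh1 were lower, at -1.27, -1.17 and -0.95, and Krt84 and Aldh1a1, below detection there, were at least 1.55-fold and 1.32-fold lower. The cornified envelope genes Sprr2f, Sprr2g, Sprr2e, Sprr2k and Lce3e, families of near-identical copies, were lower on the stabilised array, at -1.85, -1.15, -1.44, -0.92 and -1.48, and higher in knockdown wounds by 1.45, 1.39, 0.94, 0.91 and 1.11. Limma's test of the difference between the 2 effects called 1 gene, Fcer1g, with a difference of 7.93 and an adjusted p of 0.0190, measured against a GFP control value below detection. For these 10 genes the adjusted p of that test was 0.703 or more. The test takes its spread from the tamoxifen groups and assumes that the lone adenovirus arrays vary like them, and it called 0 genes whichever tamoxifen array was left out.

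**Figure D3:**
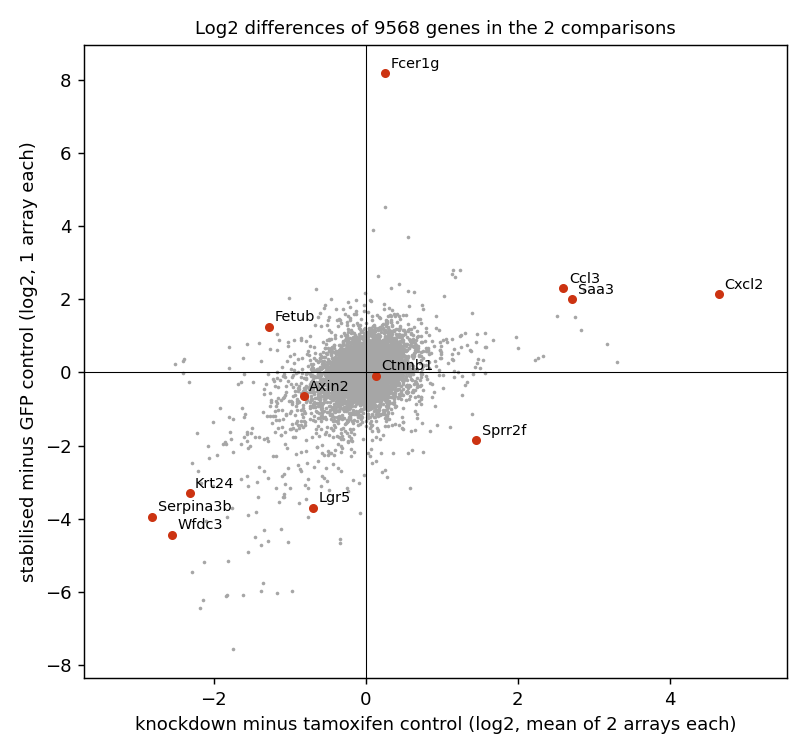
Each point is 1 of 9568 genes, with the log2 difference between knockdown and tamoxifen control means (2 arrays each) on the horizontal axis and that between the stabilised and GFP control arrays (1 each) on the vertical axis. Named genes are in red. Most of the spread runs from lower left to upper right, with an r of 0.425, and Fcer1g stands apart at 8.18 on the vertical axis, with a GFP control value below detection.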

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

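Of the tests in this part, those on H2-Ea alone and on Fcer1g alone were chosen after the values were seen, as was the definition of a single-array gene. Fcer1g was singled out because its 2 effects differed by 7.93 on the log2 scale (limma adjusted p = 0.0190). The adenovirus arms of that test hold 1 array each, so its p uses the spread of the tamoxifen arrays and does not measure that of the adenovirus pair, and the call ended whichever tamoxifen array was left out. It was 0.25 higher in knockdown than in control wounds and at least 120-fold higher on the stabilised than on the GFP control array, where its single probe was below detection, so 7.93 is itself measured against background.

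Fcer1g is 1 of 30 genes that set 1 adenovirus array apart from the 5 others, as are H2-Ea, on only on the stabilised array, and Ifi205, off only on the GFP control array, but also Hoxc10 and Fgfr1op2, and cell number was weighed for the first 3 alone. The number of antigen-presenting cells is argued against for H2-Ea, since its partners H2-Aa, H2-Ab1, H2-Eb1 and Cd74 differed by at most 1.02 where H2-Ea differed at least 173-fold, and the number of myeloid cells for Fcer1g, since the 20 other macrophage markers had a median of 0.76 and a 90th percentile in absolute size of 1.45, and 19 of them were detected on the GFP control array. For the 3 genes as a set, cell number stays open, because Retnla, a macrophage marker, differed by 3.90 and Ifi205 is known only as at least 10.9-fold. Retnla, however, stood out on the stabilised array, at 11.88, and its 7.98 on the GFP control array lay within the tamoxifen arrays' 6.11 to 8.83. It therefore says nothing of fewer cells on the GFP control array, where Fcer1g and Ifi205 were off. A strain variant may account for H2-Ea, a gene that C57BL/6 mice are known not to express and that was above background on 1 of 6 arrays, but the wider prediction that such genes neighbour each other in the genome was left undecided, with 13.3% of 11 and 19 single-array genes of the GFP control and stabilised arrays within 2 Mb of another, against a median of 6.67% and an upper limit of 20% in random draws. If the 2 adenovirus mice differ in background, any gene of that comparison could carry it, and an effect of stabilised beta-catenin on these genes cannot be told apart from it with 1 array per group.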

How the results depend on the processing

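The count of 0 knockdown genes held under each setting except leaving out a tamoxifen array, which gave 0 to 7. Over the normalizations, filters, probe rules and variance models, 4.10% to 4.75% of the genes had an unadjusted p under 0.05, and 1.89% with treat at a minimum of 1.2-fold. The mice's ages match by replicate number, with only 2 pairs, and same-numbered arrays deviated together with a correlation of 0.127 across genes. With a replicate block 755 genes, or 7.66%, had an unadjusted p under 0.05, where chance gives 493. The shortfall against chance in the main fit therefore does not hold with the block. The block left the knockdown count at 0 and the list count at 14, and took the genes whose 2 effects differ from 1 to 0. That count was 2 with no filter, which admits H2-Ea, and 0 whichever tamoxifen array was left out. The 14 lists became 0 with an estimated correlation and 0 with fry, and 10 to 15 when an array was left out. The cell cycle list ran from -0.022 without tamoxifen control replicate 2 to 0.49, and the neutrophil list from -0.22 without knockdown replicate 2 to 1.78. The log2 fold change of Ctnnb1 ran from -0.15 to 0.41, and the correlation between comparisons from 0.236 to 0.448, or 0.401 without the muscle lists, a setting chosen after seeing the data.

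The 768 genes at least 2-fold different between the adenovirus arrays became 411 with normexp and an offset of 50, and 312 with no background correction, both of which compress dim genes. They became 450 with detection on all arrays compared, or 452 among genes detected on both arrays, the last chosen after seeing the data. Counting every probe gave 1268, a 1.5-fold threshold 1977, and the 6-array limma fit, whose spread comes from the tamoxifen groups alone, 2, H2-Ea and Fcer1g. The Wnt pathway median of the adenovirus pair turned to 0.0084 with no filter and 0.026 with detection on both arrays; the cause was not tested. The named knockdown genes kept their sign in all 180 values over the settings, which their choice by size and by groups that do not overlap largely fixed in advance. For such a gene, leaving out an array cannot reverse the sign. The named adenovirus genes detected on both arrays kept theirs too, and 60 of their values stayed and 20 moved in size.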

Other observations

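The tests on muscle content, on labels and on the chemokines alone in this part were chosen after the values were seen, as were the genes named here. All 6 measured Klk1b genes, glandular kallikreins that are near-identical copies, were lower in knockdown wounds, with a median log2 fold change of -2.40, groups that did not overlap and limma adjusted p of 0.254 to 0.932. Klk1b21 read 7.86 ± 0.07 against 10.25 ± 0.00352 (SD, n = 2 each) and Klk1b24 had a log2 fold change of -2.09, the smallest adjusted p of the comparison at 0.254 for both. On the adenovirus arrays Klk1b21 read 5.98 and 6.34. Best1, encoding a chloride channel, read 7.09 to 7.95 on the tamoxifen arrays and 4.67 and 4.87 on the adenovirus arrays, a difference that goes with line, sex and treatment alike. Dct, a melanin enzyme, was at -2.10 in knockdown and at least 6.04-fold lower on the stabilised array.

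Muscle, sebaceous and Wnt target lists had medians below 0 both in knockdown wounds, where each had an adjusted p of 0.606 with an estimated correlation in camera, and on the array labelled stabilised, although the design changes beta-catenin in opposite directions; of the follicle list only 3 genes were measured in knockdown, and 1 of them, Krt84, went in opposite ways. Tissue composition along the 2 within-group differences, control 1 against 2 and knockdown 1 against 2, is argued against as the whole cause. The correlation of the 2 effects was 0.400 after these were regressed out, against 0.425 before. That regression removes only the 2 mixtures of tissue that these differences hold. Tissues that vary apart from them, and composition that differed only between groups, were not covered and stay open. Without knockdown replicate 1 the correlation was lower, as given above. For muscle alone the 2 knockdown arrays differed by a median of -2.08, so the muscle content of the piece taken may account for that part. A mislabelled adenovirus array cannot be told apart from a lower Wnt readout or from composition that the regression did not cover. Of 14 Wnt targets, 13 were lower on the array labelled stabilised, and no Ctnnb1 probe is known to lie in the floxed exon. An effect of beta-catenin on muscle or skin appendages stays open as well.

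Knockdown replicate 2, whose single-gene values had been seen before this test was written, stood apart in chemokine and haemoglobin genes, with Ccl4 at 15.01 against 9.81 on replicate 1 and Il1b at 13.64 against 8.65. Inflammatory cells in that wound may account for the chemokines: the neutrophil list, which holds none, was higher than on replicate 1 by a median of 1.72, at the 100th percentile of random lists, where the younger control array differed from the older by 0.56. That percentile does not allow for markers that vary together between wounds. Blood in the wound cannot be told apart from other causes of the haemoglobin values, since of the other erythroid genes listed only Alas2 was detected: at 8.13 on that array and below detection on the 3 other tamoxifen arrays it goes with blood, but it is 1 gene. The knockdown replicates also differ in age, 2 and 5 months, so an effect of age on the response to knockdown was not tested and stays open.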
